A study of Mus musculus with 28 samples.

How the data were processed

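Nuclear RNA from mouse liver was sequenced in 28 libraries of 8 groups, selected for polyadenylated RNA and prepared as stranded libraries per the labels. The only file analysed here is a table of the authors' own comparisons: 24197 RefSeq genes, each with values for 5 comparisons and pooled values per group. Reads were aligned with TopHat2 2.0.13 to the mouse genome build mm9 and counted with featureCounts 1.4.6-p5, per the submitters' processing notes, which also name edgeR without a version. Counting covered the gene body, per the file headers. The FPKM values (fragments per kilobase, scaled to library size) are 1 value per group made by the authors, and how replicates were combined is not given in the sources used here. The fold change is the authors' signed score, numerator over denominator where positive and the negative inverse where negative, and it carries a scaling between groups beyond the FPKM ratio. The p-values are the authors' edgeR values, and their pile-up at 1 and tied runs in the deposited table are those of Benjamini-Hochberg adjusted values, so they are called adjusted p here.

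No column holds values of a single library. Total counts per library, standard errors, standard deviations and any n behind a value could therefore not be computed, the depth is unknown, and the edgeR and limma fits fixed in the design before the data were examined could not be made. The comparisons rest on the deposited fold changes and adjusted p instead. Replicates are separate mice per the labels, so the authors' p-values measure the spread between mice within these groups.

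A gene was called higher or lower at a deposited adjusted p under 0.05, and separately with a change of at least 2-fold. The counts of called genes equal those in the file header in all 5 comparisons. The design listed the 4 comparisons of TCPOBOP with vehicle. The fifth, TCPOBOP-treated males of the high over the low corn oil regimen at 8 weeks, was deposited by the authors and added after the table was seen. The 4 treatment comparisons share no library, whereas the fifth uses the TCPOBOP libraries of both 8-week comparisons. Signed folds were converted to log2 fold changes, which are the authors' values on another scale. Of the 24197 genes, 4917 were listed at 0 in all groups, and 1285 carry names that start with Mir or Snor, small RNAs that can lie within longer host genes.

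The fixed rule for named genes took the 8 largest rises and 8 largest falls of each TCPOBOP comparison, the 5 largest in each direction of each other contrast, the 4 members with the smallest adjusted p of each list with a called member, and always Cyp2b10, Nr1i3 and the X and Y linked genes. Its limit of 2 CPM in the higher group became 2 FPKM, and its limit of no overlap between libraries could not be applied. Genes outside the rule, among them all clock genes and the list members given for the comparison of both TCPOBOP groups other than Saa1, Saa2, Cyp2b10 and Nr1i3, were chosen after their values were seen. The values of 1 gene are not reported here, though counts, list tests and medians include it.

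The 24 gene lists were written before the data were examined: CAR-responsive phase I enzymes, conjugation enzymes, hepatic drug and bile transporters, cell cycle and DNA replication, growth arrest with p53 and oncofetal genes, male-biased and female-biased liver genes, fatty acid and triglyceride synthesis, fatty acid oxidation, lipid uptake and droplets, cholesterol synthesis, bile acid synthesis, glucose metabolism, nuclear receptors, pericentral and periportal hepatocyte genes, acute phase genes, markers of Kupffer cells, of lymphocytes and neutrophils, of stellate cells and matrix, of endothelium and of cholangiocytes, blood and nuclear RNA markers, and the X and Y linked check. Hmgcs1 was listed at 0 in all groups, and Ighm and Ly6g had no matching symbol. The planned fry and camera tests need library values. In their place the median log2 fold change of a list was set against 10000 random lists of the same size, drawn from genes above 0 FPKM in the same 20 bins of mean expression, with a two-sided permutation p whose smallest value is 0.0002 and Benjamini-Hochberg adjustment over 23 lists per comparison. Genes are not independent replicates, and co-regulation within a list makes these p-values too small. In the blood and nuclear RNA list Hbb-b1 and Hbb-bs had the same log2 fold changes at 2 weeks, as did Hbb-b2 and Hbb-bt. Each was counted as a separate member, so the counts and p-values of that list treat these pairs as independent genes. Member counts adjusted over the list alone use p-values recovered from the adjusted ones, which are upper bounds within tied runs, so those counts are lower bounds. In 15 list tests median and mean had opposite signs, and none of these passed its test.

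A difference between 2 responses was tested by an approximation added after the table was seen. The standard error of each log2 fold change was taken from its recovered p-value by a normal approximation, no smaller than the median of genes of like expression, and the difference of both log2 fold changes was divided by its combined error. Genes needed at least 0.5 FPKM in the highest of the 4 groups and a value above 0 in each. Tested on simulated data over 12253 genes with the error sizes of the comparison of males with females, it recovered 10% of log2 differences of 1, 69% of 2 and 95% of 3, with 2.79% false calls. Over 12353 genes for high against low corn oil these shares were 5%, 68% and 92%, with 2.94% false calls. Both simulations took the recovered standard errors as the true ones and drew normal noise in place of counts. They cannot show whether those errors are right for the deposited values, nor the false share among the real calls. Of the simulated random lists of 20 genes 4.2% fell under 0.05, and all lists shifted by 1 on the log2 scale were called.

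Sex ratios and vehicle ratios were computed from the pooled FPKM values with a pseudocount of 0.1, for genes of at least 2 FPKM in the higher group, and have no test because the authors deposited no such comparison. The fold change on this scale understates the change of low genes. Sex bias was defined as a ratio of at least 2-fold in 2-week vehicle mice, since the adjusted p of the fixed definition could not be had. A ratio of 4-fold had been looked at first, and both results were known when the 2-fold ratio of the design was taken as the main one. Association with sex bias was tested with a two-sided Fisher exact test, overlap of calls with a one-sided Fisher exact test.

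Alternatives were a stricter adjusted p of 0.01, FPKM ratios in place of the deposited fold, a pseudocount of 1 and FPKM minima. Further ones were other definitions of sex bias, other settings of the approximate test and other random lists. These random lists came from genes of at least 0.5 FPKM in any group, and list members below it were left out too. Coordinates are not given because the reference used here is another build, GRCm38, than the authors' mm9. Symbols of 22869 genes matched its gene table. Paralogs and pseudogenes of the Cyp2c, Cyp3a, Mup, Gst and globin families share reads, and overlapping genes share positions, so their values are uncertain. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.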

Results

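Gene expression was measured in liver nuclei of outbred CD-1 mice given TCPOBOP, a synthetic agonist of the constitutive androstane receptor (CAR, encoded by Nr1i3), or vehicle. CAR is a nuclear receptor known to induce hepatic drug-metabolising enzymes. At 2 weeks after a dose of 3 mg/kg in a low volume of corn oil (4 µl per g body weight, 10% DMSO), 4 TCPOBOP and 3 vehicle mice of each sex were studied, aged 9 to 10 weeks. At 8 weeks, males of the high corn oil regimen (20 µl per g, 2% DMSO) comprised 3 TCPOBOP and 3 vehicle mice, with later doses of 1 mg/kg. Males of the low corn oil regimen comprised 4 TCPOBOP mice, with later doses of 1.5 mg/kg, and 4 vehicle mice treated for 4 to 8 weeks. The 8-week mice were aged 15 to 16 weeks, except for 2 of the low corn oil vehicle mice, which were 11 to 12 weeks old. Each library came from 1 liver, giving 28 libraries in 8 groups. The values are the authors' pooled values per group, without standard errors, so no spread between mice accompanies them, and the depth of the libraries is unknown.

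The X and Y linked genes followed the labelled sex. Xist, the long RNA of the inactive X chromosome, stood at 142 FPKM in vehicle and 95.2 FPKM in TCPOBOP females and at most at 0.233 FPKM in any male group of the authors' deposited table. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d lay between 1.86 and 31.0 FPKM in the male groups and at or under 0.0472 FPKM in the female groups of the authors' deposited table.

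**Figure D1:**
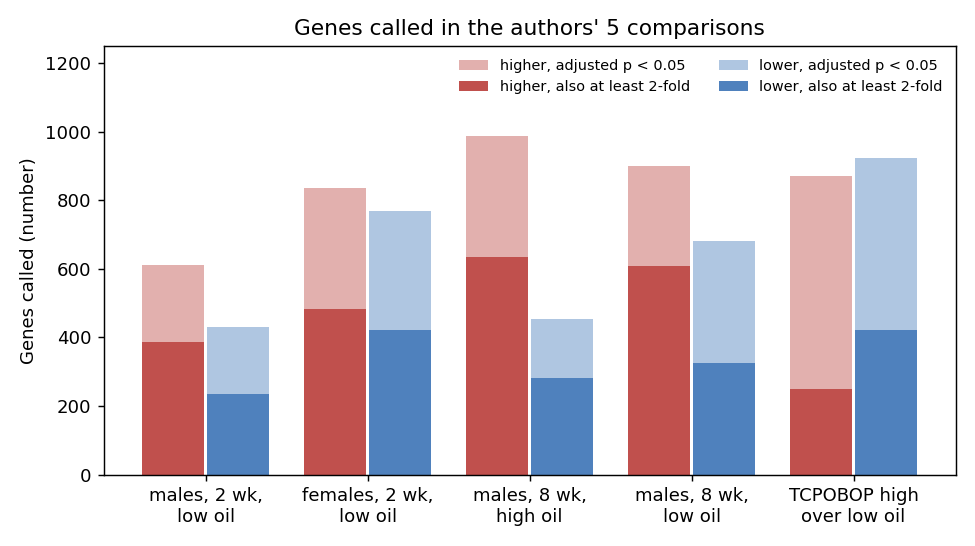
Number of genes called higher or lower at an adjusted p under 0.05 in each of the authors' 5 comparisons (pale bars), and of those with a change of at least 2-fold (dark bars). Higher genes ranged from 610 in 2-week males to 987 in 8-week males under high corn oil.

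The first comparison asked which liver genes responded to CAR activation in males after 2 weeks. Drug-metabolism genes rose. Cyp2b10, the prototypical CAR target, rose 133-fold from 2.41 to 335 FPKM (adjusted p = 9.37e-107), and Cyp2c55 rose 151-fold to 110 FPKM in the authors' deposited table. Nr1i3, the gene of the receptor itself, fell by 2.32 on the log2 scale, from 147 to 31.0 FPKM in the authors' deposited table. Of 20 CAR-responsive phase I enzymes 17 rose and none fell (18 adjusted over the list alone). Their median log2 fold change was 1.88, with a permutation p of 0.0002, the smallest that the random lists can give, or 0.00092 after adjustment over 23 lists. Among 26 conjugation enzymes 13 rose and 1 fell (15 and 1 adjusted over the list alone), with the same p and a median of 0.86. Gstm3, a glutathione transferase, rose by 4.54, Sult1d1 by 2.36 and Gstt3 by 3.56 on the log2 scale in the authors' deposited table. Of 18 transporters 1 rose and 2 fell, Abcc4 by 2.63 upward and the sterol exporters Abcg5 and Abcg8 to log2 fold changes of -1.20 and -0.91 in the authors' deposited table.

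Cell cycle genes rose as a group in 2-week males, with 9 of 30 higher and none lower (14 adjusted over the list alone, permutation p = 0.0002, adjusted p = 0.00092). Ccnd1, which encodes cyclin D1, rose from 1.38 to 4.89 FPKM, Cdc20 from 0.194 to 2.05 FPKM, and the proliferation marker Mki67 from 0.177 to 0.672 FPKM in the authors' deposited table. Growth arrest and oncofetal genes had 4 of 16 members higher and none lower (4 and 1 adjusted over the list alone, permutation p = 0.0016, adjusted p = 0.00526). They were led by Gadd45b, a stress-induced growth regulator, at a log2 fold change of 4.38, and Lcn2 at 2.62 in the authors' deposited table. Pericentral hepatocyte genes moved the other way. Of 16 measured, 7 fell and 2 rose (11 and 3 adjusted over the list alone, median -0.68, permutation p = 0.0002, adjusted p = 0.00092), and the same list contains the CAR target Cyp1a2, which rose. Slc1a2, a glutamate transporter, fell by 2.45, Lgr5 by 2.36 and Oat by 1.93 on the log2 scale in the authors' deposited table. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 10.6 to 2.91 FPKM in the authors' deposited table.

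Among lists of other cell types in 2-week males, Kupffer cell and macrophage markers had 4 of 19 members higher (10 adjusted over the list alone, permutation p = 0.0004, adjusted p = 0.00153), among them Gpnmb, which rose from 0.0161 to 0.245 FPKM in the authors' deposited table. Lymphocyte and neutrophil markers passed the list test (permutation p = 0.003, adjusted p = 0.00767) with 1 of 17 members called, S100a8, which rose from 0.236 to 18.3 FPKM in the authors' deposited table. Blood and nuclear RNA markers were higher (3 of 10, 6 adjusted over the list alone, permutation p = 0.0002, adjusted p = 0.00092), with Hbb-b1 at a log2 fold change of 0.90 and the nuclear RNA Neat1 at 1.19 in the authors' deposited table. Cholangiocyte markers had a median of -0.59 with no member called (permutation p = 0.0048, adjusted p = 0.011). Female-biased genes had 5 of 30 members higher and none lower (5 adjusted over the list alone, permutation p = 0.0022, adjusted p = 0.00633), Cyp2b13 the highest with a rise from 0.131 to 25.8 FPKM in the authors' deposited table. That list call was lost when FPKM ratios with a pseudocount of 0.1 replaced the deposited folds (adjusted p = 0.369). The other 13 lists did not pass, with permutation p of 0.0288 to 0.931 and adjusted p of 0.0602 to 0.931. Within them (adjusted over the list alone in parentheses) lipid uptake and droplet genes had 6 of 22 higher and 2 lower (6 and 2), fatty acid synthesis 3 of 21 higher (5 and 1), fatty acid oxidation 2 of 25 lower (1 and 4), and acute phase genes 7 of 20 higher and 3 lower (8 and 4). Male-biased genes had 1 of 22 higher and 3 lower (1 and 4) and stellate cell and matrix markers 3 of 20 higher (4 and 0). Bile acid genes had 4 of 17 lower (1 and 5), glucose genes 1 of 17 higher and 1 lower (2 and 1), nuclear receptors 2 of 24 higher and 2 lower (2 and 2), and periportal genes 1 of 17 lower (0 and 1). Transporters had the calls above (2 and 4), and none was called of 18 endothelial (0 and 1) or 23 cholesterol genes (0 and 0). Fgf21, a fasting hormone, fell from 1.78 to 0.167 FPKM, and Thrsp, a regulator of lipogenesis, rose by 2.04 on the log2 scale in the authors' deposited table.

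In all, 610 genes were higher and 431 lower in 2-week males, 387 and 236 of them by at least 2-fold. The largest rises by the fixed rule also included Moxd1 (355-fold, from 0.0064 FPKM), Krt4 (223-fold), Cyp2c66 (to 2.78 FPKM) and the pancreatic lipase relative Pnliprp1 (161-fold to 17.2 FPKM) in the authors' deposited table. The largest falls were Dmbt1 (from 5.97 to 0.156 FPKM, adjusted p = 0.0317), BC089597 (from 42.5 to 3.75 FPKM), AW549542, Adh6-ps1, H2-Ea-ps and Obp2a, with log2 fold changes between -5.30 and -2.97 in the authors' deposited table. With FPKM ratios and a pseudocount of 1 in place of the deposited folds, the 2-fold counts were 166 and 58. Low genes then count for less and the authors' scaling between groups is dropped, and the share of each was not tested.

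In females after 2 weeks the drug-metabolism genes rose as well. Cyp2b10 rose 67.9-fold from 7.25 to 499 FPKM (adjusted p = 8.92e-40), Cyp2c55 rose 216-fold to 165 FPKM and Akr1b7 112-fold to 18.2 FPKM in the authors' deposited table. Of the 20 CAR-responsive phase I enzymes 19 rose and none fell (19 adjusted over the list alone, median 3.14), and of 26 conjugation enzymes 20 rose and none fell (21 adjusted over the list alone, median 1.15), both with a permutation p of 0.0002 and an adjusted p of 0.00115. Gsta1 rose by 6.23 and Gstm3 by 5.49 on the log2 scale, while Nr1i3 fell from 176 to 59.7 FPKM in the authors' deposited table. Cell cycle genes had 1 of 30 members higher, Rrm2, and 1 lower, Mybl2 (the same adjusted over the list alone). Their median of 0.22 passed against random lists (permutation p = 0.0126, adjusted p = 0.0263). When the list and the random lists kept only genes of at least 0.5 FPKM, the median was 0.12 and did not pass (adjusted p = 0.283). Growth arrest and oncofetal genes had 5 of 16 higher and 1 lower (5 and 1 adjusted over the list alone, permutation p = 0.0002, adjusted p = 0.00115). With the same minimum of 0.5 FPKM their median went from 0.60 to 0.18 and the call was lost (adjusted p = 0.283). Lcn2 rose from 3.17 to 29.7 FPKM and Gadd45b from 1.79 to 20.6 FPKM, whereas Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 2.26 on the log2 scale in the authors' deposited table.

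Both zonation lists fell in females. Periportal genes had 7 of 17 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.54, permutation p = 0.0002, adjusted p = 0.00115), and pericentral genes 5 of 16 lower and 2 higher (6 and 2 adjusted over the list alone, median -0.49, permutation p = 0.0008, adjusted p = 0.00204). Etnppl fell from 13.5 to 2.92 FPKM, Tat by 1.30, Lgr5 by 2.00 and Oat by 1.47 on the log2 scale in the authors' deposited table. Glucose genes did not pass as a list, with 1 of 17 higher and 3 lower. Within it G6pc, which encodes glucose-6-phosphatase, fell from 178 to 25.0 FPKM, the glycogen-targeting subunit Ppp1r3c from 18.1 to 2.93 FPKM and Pck1 from 278 to 112 FPKM in the authors' deposited table. Lipid uptake and droplet genes had 8 of 22 higher and 3 lower (the same counts adjusted over the list alone, median 0.44, permutation p = 0.0006, adjusted p = 0.00173). Apoa4 rose from 47.4 to 519 FPKM, while G0s2 fell by 1.34 and Plin5 by 1.02 on the log2 scale in the authors' deposited table.

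Acute phase genes passed in females with 7 of 20 higher and 2 lower (8 and 2 adjusted over the list alone, permutation p = 0.0072, adjusted p = 0.0166). Haptoglobin (Hp) rose from 353 to 1331 FPKM and Orm2 from 3.09 to 34.6 FPKM, and Itih3 fell by 1.96 on the log2 scale in the authors' deposited table. Markers of Kupffer cells (2 of 19 higher, 5 adjusted over the list alone, permutation p = 0.0006, adjusted p = 0.00173), of lymphocytes and neutrophils (2 of 17 higher, 2 adjusted over the list alone, permutation p = 0.0004, adjusted p = 0.00173) and of stellate cells and matrix (3 of 20 higher, 4 higher and 1 lower adjusted over the list alone, permutation p = 0.0138, adjusted p = 0.0265) were shifted upward. The stellate call was lost with a pseudocount of 1 (adjusted p = 0.0611). The called members were Ccr2, Lyz2, S100a8, Cd74 and the collagens Col1a1, Col3a1 and Col1a2, with log2 fold changes between 0.66 and 5.54 in the authors' deposited table. Blood and nuclear RNA markers were lower (3 of 10, 1 higher, 4 and 1 adjusted over the list alone, permutation p = 0.0006, adjusted p = 0.00173). Hbb-b2 and Hbb-bt, which carry identical values and share reads with other globins, fell by 5.88 on the log2 scale from 3.71 FPKM in the authors' deposited table. Hbb-b1, at 42.1 FPKM in vehicle, had a log2 fold change of -0.55 that was not called in the authors' deposited table. Hbb-bs had the same log2 fold change, which was also the median of the list. The remaining 11 lists did not pass, with permutation p of 0.0488 to 0.675 and adjusted p of 0.0863 to 0.675. Of these (adjusted over the list alone in parentheses) transporters had 4 of 18 higher and 3 lower (6 and 4), male-biased genes 6 of 22 higher and 6 lower (7 and 8), female-biased genes 6 of 30 higher and 8 lower (7 and 9) and fatty acid synthesis 3 of 21 higher and 1 lower (5 and 2). Fatty acid oxidation had 1 of 25 higher and 2 lower (1 and 4), cholesterol genes 1 of 23 higher (4 and 0), and bile acid genes 1 of 17 higher and 2 lower (1 and 2). Glucose genes had the calls above (4 and 5), nuclear receptors 2 of 24 higher and 2 lower (3 and 4), endothelial markers 1 of 18 higher (1 and 0) and cholangiocyte markers 1 of 12 lower (0 and 1).

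Females had 836 genes higher and 770 lower, 484 and 422 of them by at least 2-fold. Of the 4 TCPOBOP libraries of females, 1 carries another set code than all other 2-week libraries, and its effect on the pooled values was not tested. Cyp2c53-ps, a pseudogene of the Cyp2c cluster, rose from 0.0496 to 53.9 FPKM and Pnliprp1 from 0.214 to 156 FPKM in the authors' deposited table. Sult1e1, an oestrogen sulfotransferase, rose 247-fold to 22.5 FPKM, and Sprr1a, listed at 0 in vehicle, stood at 4.57 FPKM in the authors' deposited table. Serpina4-ps1 fell from 439 to 2.68 FPKM, Hsd3b5 from 8.60 to 0.0861 FPKM and Cyp2c69 from 90.4 to 1.12 FPKM in the authors' deposited table. The 2-fold counts were 257 and 128 with FPKM ratios and a pseudocount of 1.

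The third comparison asked about 8 weeks of treatment in males under the high corn oil regimen. Cyp2b10 rose 231-fold from 1.72 to 389 FPKM (adjusted p = 1.66e-74), Cyp2c55 214-fold to 111 FPKM and Gstm3 42.8-fold to 387 FPKM in the authors' deposited table. Of 20 phase I enzymes 17 rose and none fell (18 adjusted over the list alone, median 2.70), and of 26 conjugation enzymes 14 rose and none fell (21 higher and 1 lower adjusted over the list alone, median 1.25), both with a permutation p of 0.0002 and an adjusted p of 0.00153. Nr1i3 fell from 115 to 25.2 FPKM in the authors' deposited table. Cell cycle genes had 11 of 30 higher and none lower (13 adjusted over the list alone, median 0.90, permutation p = 0.0002, adjusted p = 0.00153). Cdc20 rose from 0.219 to 2.67 FPKM and Ccnb1, which encodes cyclin B1, from 0.0618 to 0.552 FPKM in the authors' deposited table. Lipid uptake and droplet genes had 7 of 22 higher and 1 lower (9 and 2 adjusted over the list alone, median 0.49, permutation p = 0.0036, adjusted p = 0.0207). Lipoprotein lipase (Lpl) rose from 1.82 to 12.5 FPKM, Apoa4 from 22.0 to 614 FPKM, and Cidec, a lipid droplet protein, 14.8-fold in the authors' deposited table. Of 25 fatty acid oxidation genes none was called, also not when adjusted over the list alone.

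Pericentral genes had 6 of 16 lower and 3 higher at 8 weeks under high corn oil (7 and 3 adjusted over the list alone), and the list did not pass (permutation p = 0.0656, adjusted p = 0.168). Slc1a2 fell from 2.10 to 0.204 FPKM and Oat from 18.4 to 2.98 FPKM, while Cyp1a2 rose 5.16-fold to 180 FPKM in the authors' deposited table. Female-biased genes had 11 of 30 higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.06 (permutation p = 0.4486, adjusted p = 0.688). Cyp2b13 rose to 23.2 FPKM, Prom1 to 3.16 FPKM and Hao2 to 2.62 FPKM, each from under 0.4 FPKM of the authors' deposited table. Growth arrest genes had 6 of 16 higher (6 adjusted over the list alone), led by Gadd45b with a rise from 0.463 to 16.1 FPKM in the authors' deposited table. Stellate cell and matrix markers had 4 of 20 higher (4 adjusted over the list alone, permutation p = 0.0066, adjusted p = 0.0304). This call was lost with a pseudocount of 1 (adjusted p = 0.0835). It was also lost when the list and the random lists kept only genes of at least 0.5 FPKM (median 0.23, adjusted p = 0.178). The called members were Col1a1, Col3a1, Col1a2 and Tagln, with log2 fold changes of 2.70, 1.01, 0.99 and 1.38 in the authors' deposited table. Macrophage markers had 3 of 19 higher, Gpnmb, Lyz2 and Trem2 (4 adjusted over the list alone). The 18 lists that did not pass had permutation p of 0.0288 to 0.979 and adjusted p of 0.101 to 0.979. Among them (adjusted over the list alone in parentheses) transporters had 6 of 18 higher and 1 lower (6 and 1), acute phase genes 6 of 20 higher and 1 lower (6 and 1) and male-biased genes 2 of 22 higher and 5 lower (4 and 5). Cholesterol genes had 3 of 23 higher (4 and 1), fatty acid synthesis 2 of 21 higher (3 and 3) and glucose genes 2 of 17 higher and 1 lower (2 and 1). Bile acid genes had 1 of 17 higher and 2 lower (1 and 2), nuclear receptors 1 of 24 higher and 2 lower (2 and 2), periportal genes 1 of 17 lower (0 and 1), and lymphocyte and neutrophil markers 1 of 17 higher (1 and 1). Endothelial markers had 1 of 18 lower (0 and 1), cholangiocyte markers 1 of 12 higher (2 and 0) and blood and nuclear RNA markers 1 of 10 lower (0 and 1).

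There were 987 genes higher and 454 lower, 635 and 283 of them by at least 2-fold. The largest rises were Prss22, Cyp2c66 and Meig1, listed at 0 in vehicle and at 5.98, 3.26 and 4.21 FPKM after TCPOBOP. Pnliprp1 rose 566-fold to 50.9 FPKM in the authors' deposited table. The level of Prss22 also differed between vehicle groups, as it stood at 7.66 FPKM in vehicle and 11.6 FPKM in TCPOBOP males at 2 weeks. The largest falls were Gm3219 (from 12.0 to 0.0823 FPKM), Susd4 (from 6.01 to 0.220 FPKM), Gm4841, Fam25c and AW549542, with log2 fold changes of -7.19 to -4.57 in the authors' deposited table. With FPKM ratios and a pseudocount of 1 the 2-fold counts were 266 and 120.

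Males treated for 8 weeks under the low corn oil regimen had higher drug-metabolism genes too. Cyp2b10 rose 96.8-fold from 2.29 to 238 FPKM (adjusted p = 7.41e-80), Cyp2c55 144-fold to 81.7 FPKM and Gstm3 23.1-fold to 304 FPKM, and Nr1i3 fell from 171 to 31.0 FPKM in the authors' deposited table. Of 20 phase I enzymes 18 rose and none fell (18 adjusted over the list alone, median 2.39), and of 26 conjugation enzymes 17 rose and none fell (21 adjusted over the list alone, median 1.10), both with a permutation p of 0.0002 and an adjusted p of 0.000657. Male-biased and female-biased genes moved in opposite directions. Of 22 male-biased genes 9 fell and none rose (12 lower and 2 higher adjusted over the list alone, median -0.76), and of 30 female-biased genes 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.85), both with a permutation p of 0.0002 and an adjusted p of 0.000657. Cyp7b1 fell from 40.5 to 12.0 FPKM, Cyp2u1 from 20.4 to 3.52 FPKM and the repressor gene Bcl6 from 21.6 to 4.24 FPKM, while Cyp2b13 rose to 17.5 and Hao2 to 3.93 FPKM in the authors' deposited table.

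Cell cycle genes had 9 of 30 higher and none lower (15 and 1 adjusted over the list alone, median 0.65), and growth arrest genes 7 of 16 higher (7 and 1 adjusted over the list alone, median 0.62), with permutation p of 0.0002 and 0.0004 and adjusted p of 0.000657 and 0.00115. Mki67 rose from 0.135 to 0.743 FPKM, Gadd45b by 4.25 on the log2 scale to 15.3 FPKM and Myc from 1.14 to 5.54 FPKM in the authors' deposited table. Both zonation lists were lower, with 9 of 16 pericentral genes lower and 3 higher (10 and 3 adjusted over the list alone) and 6 of 17 periportal genes lower (8 adjusted over the list alone, median -0.75), each with a permutation p of 0.0002 and an adjusted p of 0.000657. Oat fell from 18.8 to 2.79 FPKM, Slc1a2 10.6-fold and the glutamine synthetase gene Glul by 1.17 on the log2 scale, and periportal Etnppl from 22.3 to 5.25 FPKM in the authors' deposited table. Lipid uptake and droplet genes had 8 of 22 higher and 2 lower (9 and 2 adjusted over the list alone, permutation p = 0.001, adjusted p = 0.0023). The fatty acid transporter Cd36 rose from 2.60 to 12.0 FPKM and Apoa4 from 30.1 to 310 FPKM, and G0s2 fell from 62.9 to 19.8 FPKM in the authors' deposited table.

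Acute phase genes had 6 of 20 higher and 1 lower (8 and 2 adjusted over the list alone, permutation p = 0.001, adjusted p = 0.0023), with Orm2 higher by 3.06 and Hp by 1.32 on the log2 scale in the authors' deposited table. Lymphocyte and neutrophil markers passed (permutation p = 0.0012, adjusted p = 0.00251) with S100a8 as the called member of 17 (1 adjusted over the list alone). Cholangiocyte markers passed (permutation p = 0.0064, adjusted p = 0.0123) with Spp1 as the called member of 12 (3 adjusted over the list alone). Their median of 0.67 became -0.17 when the list and the random lists kept only genes of at least 0.5 FPKM (adjusted p = 0.613). Macrophage markers did not pass as a list, but did with FPKM ratios and a pseudocount of 1 (adjusted p = 0.0299). Of these markers 3 of 19 were higher. Gpnmb rose 25.5-fold to 0.372 FPKM, Trem2 5.03-fold to 0.450 FPKM and Spp1 from 6.78 to 21.8 FPKM in the authors' deposited table. Stellate cell and matrix markers had 5 of 20 higher and 2 lower, with Col1a1 rising from 0.648 to 3.14 FPKM and Acta2 by 1.59 on the log2 scale in the authors' deposited table. The 11 lists that did not pass had permutation p of 0.044 to 0.917 and adjusted p of 0.0778 to 0.917. Bile acid genes had the lowest, with 4 of 17 lower and 1 higher (adjusted over the list alone 6 and 1). The others (higher and lower adjusted over the list alone in parentheses) were transporters with 3 of 18 higher and 4 lower (5 and 4), fatty acid synthesis with 4 of 21 higher (6 and 3), fatty acid oxidation with 1 of 25 higher and 2 lower (3 and 3) and nuclear receptors with 2 of 24 higher and 2 lower (2 and 4). Glucose genes had 1 of 17 lower (0 and 2), endothelial markers 1 of 18 lower (0 and 2), and blood and nuclear RNA markers 1 of 10 lower (0 and 1). The macrophage and stellate lists had the calls above (3 and 0, 6 and 2), and none of 23 cholesterol genes was called (0 and 0).

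The low corn oil comparison called 900 genes higher and 680 lower, 609 and 324 of them by at least 2-fold. Cdh9 and Meig1, listed at 0 in vehicle, stood at 2.32 and 3.54 FPKM after TCPOBOP, and Sult1e1 rose 168-fold to 2.38 FPKM in the authors' deposited table. Obp2a fell from 3.98 to 0.110 FPKM, Derl3, a factor of protein degradation at the endoplasmic reticulum, from 18.2 to 0.670 FPKM and Zbtb7c 16.8-fold in the authors' deposited table. With FPKM ratios and a pseudocount of 1 the 2-fold counts were 224 and 112. All libraries of this comparison belong to 1 library set, which holds no library of the other 3 TCPOBOP comparisons, and its vehicle mice were partly younger.

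**Figure D2:**
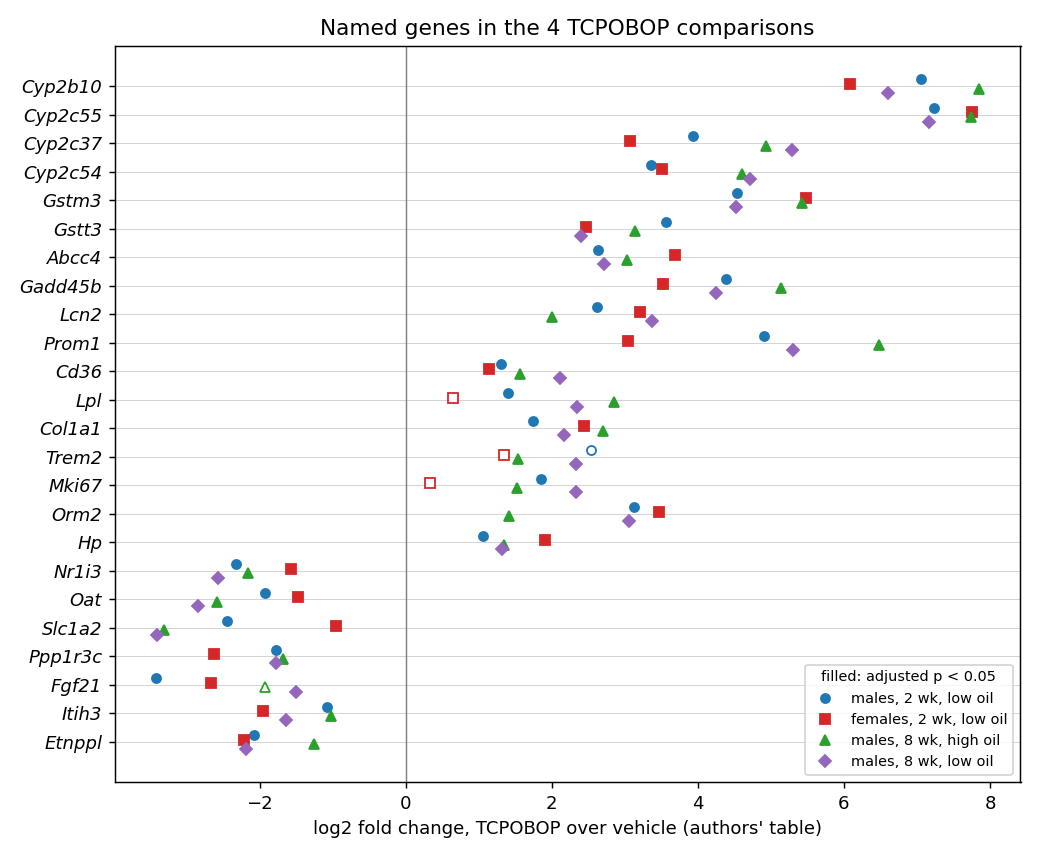
Log2 fold changes of 24 named genes (x axis) in the 4 TCPOBOP comparisons, as given in the authors' table; filled symbols have an adjusted p under 0.05. Cyp2b10 lay between 6.09 and 7.85 and Nr1i3 between -2.57 and -1.57.

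The responses overlapped. In all 4 comparisons 232 genes were higher and 76 lower, 167 and 41 of them by at least 2-fold each time. Males and females at 2 weeks shared 346 higher genes, against 29.5 for independent lists, and 190 lower genes (one-sided Fisher exact p = 9.28e-146). Both 8-week comparisons shared 488 higher genes, against 51.1, and 210 lower genes, against 17.8. Between 0 and 7 genes called in 1 comparison were called the opposite way in the other. Log2 fold changes of the 6 pairs were correlated across genes of at least 1 FPKM in a group. Pearson's r lay between 0.649 and 0.772 and Spearman's rho between 0.56 and 0.7, where genes are not independent replicates. S100a8 rose in all 4 comparisons, by 6.20, 5.54, 3.85 and 2.52 on the log2 scale in 2-week males, 2-week females and 8-week males under high and low corn oil in the authors' deposited table.

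**Figure D3:**
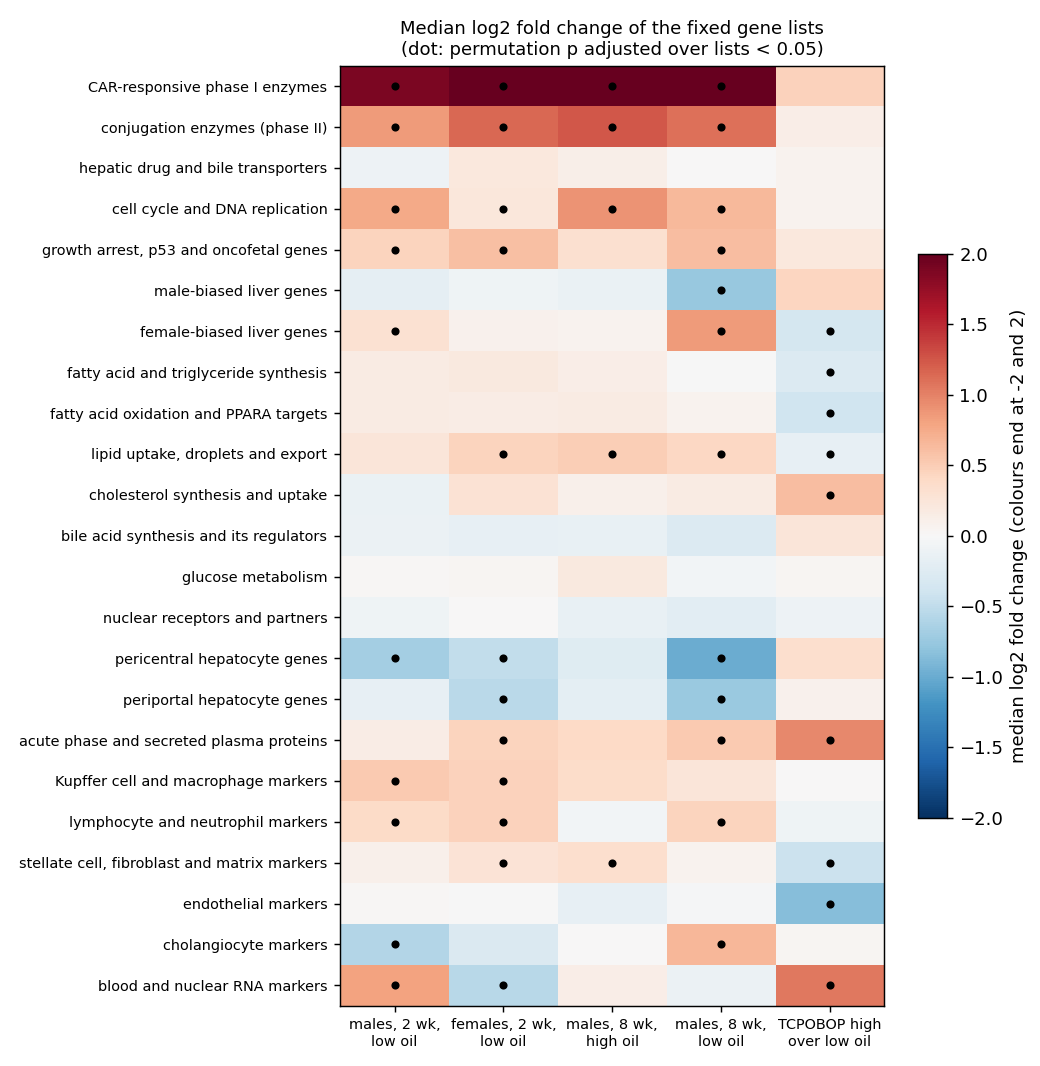
Median log2 fold change of each fixed gene list (rows) in the authors' 5 comparisons (columns); colours end at -2 and 2, and a dot marks a permutation p, adjusted over lists, under 0.05. Phase I and conjugation enzymes had medians from 0.86 to 3.14 in the 4 TCPOBOP comparisons.

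The deposited comparison of both 8-week TCPOBOP groups, high over low corn oil, called 870 genes higher and 922 lower, 249 and 423 of them by at least 2-fold, or 61 and 109 with FPKM ratios and a pseudocount of 1. Acute phase genes were higher under high corn oil, with 13 of 20 called and none lower (16 adjusted over the list alone, median 0.96, permutation p = 0.0002, adjusted p = 0.00092). The serum amyloid genes Saa1 and Saa2 stood at 438 and 251 FPKM under high against 39.3 and 20.4 FPKM under low corn oil. Hp stood at 2189 against 952 FPKM in the authors' deposited table. Fgl1, which is not on the list, stood at 139 against 15.1 FPKM in the authors' deposited table. Cholesterol synthesis genes had 9 of 23 higher and 1 lower (13 and 1 adjusted over the list alone, median 0.61, permutation p = 0.0004, adjusted p = 0.00153), among them Fdps by 1.14 and Ebp by 1.09 on the log2 scale in the authors' deposited table. Endothelial markers were lower, with 11 of 18 called and none higher (14 adjusted over the list alone, median -0.85, permutation p = 0.0002, adjusted p = 0.00092). Flt1 had a log2 fold change of -1.30, Kdr, a receptor of vascular growth factor, of -1.07 and Tek of -0.94 in the authors' deposited table.

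Stellate cell and matrix markers had 6 of 20 lower and 1 higher in the same comparison (8 and 1 adjusted over the list alone, permutation p = 0.0014, adjusted p = 0.00403), with Rgs5 at -1.46 and Timp1 at 1.82 on the log2 scale in the authors' deposited table. Haemoglobin genes moved the other way. Blood and nuclear RNA markers had 4 of 10 higher (5 adjusted over the list alone, permutation p = 0.0002, adjusted p = 0.00092), with Hbb-b1 at 28.7 against 15.1 FPKM and Hba-a1 at 20.6 against 10.9 FPKM in the authors' deposited table. Fatty acid oxidation (2 of 25 lower, 4 adjusted over the list alone) and fatty acid synthesis genes (3 of 21 lower and 1 higher, 5 and 2 adjusted over the list alone) had medians of -0.39 and -0.27, each with a permutation p of 0.0002 and an adjusted p of 0.00092. Cyp4a14 had a log2 fold change of -2.94 and Gpam of -1.56 in the authors' deposited table. Female-biased genes (2 of 30 lower) and lipid uptake genes (1 of 22 higher, 1 lower) (the same counts and 2 and 1 adjusted over the list alone) passed with permutation p of 0.0006 and 0.0094 and adjusted p of 0.00197 and 0.024, calls lost with FPKM ratios and a pseudocount of 0.1 (adjusted p = 0.46 and 0.13). Of the 20 phase I enzymes 6 were higher (8 adjusted over the list alone, permutation p = 0.258, adjusted p = 0.312), with Cyp2b10 1.81-fold higher in the authors' deposited table. Nr1i3 was not called. The 14 lists that did not pass had permutation p of 0.0328 to 0.939 and adjusted p of 0.0754 to 0.939. Besides phase I they were (higher and lower adjusted over the list alone in parentheses) male-biased genes with 5 of 22 higher (8 and 0), pericentral genes with 4 of 16 higher (4 and 0), and growth arrest genes with 3 of 16 higher and 1 lower (3 and 1). Conjugation enzymes had 1 of 26 higher and 3 lower (1 and 3) and transporters 2 of 18 higher and 2 lower (2 and 4). Periportal genes had 2 of 17 higher and 1 lower (2 and 1), glucose genes 2 of 17 lower (1 and 3), nuclear receptors 1 of 24 higher and 1 lower (1 and 1), bile acid genes 1 of 17 higher (1 and 0) and lymphocyte and neutrophil markers 1 of 17 higher (1 and 0). None was called of 30 cell cycle genes (0 and 0), 19 macrophage markers (0 and 0) or 12 cholangiocyte markers (1 and 1).

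The library set and the later dose (1 mg/kg under high and 1.5 mg/kg under low corn oil) also differ between the groups of that comparison, so regimen and library set cannot be told apart in it. Vehicle males of both regimens, compared by pooled FPKM without a test, had 173 of 8715 genes at least 2-fold higher and 168 lower under high corn oil. Among these Saa1 stood at 359 against 18.8 FPKM and Cish, a feedback inhibitor of growth hormone and cytokine signalling, at 32.3 against 1.07 FPKM in the authors' deposited table. Prss22 and D14Ertd670e, listed at 0 under low corn oil with TCPOBOP, stood at 5.98 and 22.9 FPKM under high, and Mup15 at 39.3 against 0.0323 FPKM in the authors' deposited table. Gm3219 and the small RNAs Mir2139 and Snord53 had log2 fold changes of -5.19, -3.58 and -4.28 in the authors' deposited table.

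Sex differences were examined at 2 weeks. By pooled FPKM ratio 135 genes were male-biased and 167 female-biased by at least 2-fold in vehicle mice, and 149 and 197 in TCPOBOP mice, of which 69 and 70 were those of the vehicle mice. The median log2 ratio of males over females of the vehicle-defined genes was 1.75 and -1.50 in vehicle and 1.32 and -0.94 in TCPOBOP mice. Genes defined by an extreme ratio drift toward 0 by chance alone when measured again. Cyp4a12a, a male-biased fatty acid hydroxylase, stood at 105 FPKM in vehicle males and 0.355 FPKM in vehicle females, and A1bg at 0.316 and 364 FPKM in the authors' deposited table. Of the fixed male-biased list Moxd1, Cela1 and Egfr had vehicle log2 ratios of 0.05, -0.06 and -0.03, and Ttc39c of the fixed female-biased list had 2.94, so these lists hold members without the named bias in these mice. Cyp2b13 narrowed from a log2 ratio of -7.88 to -2.25 and Cyp2c69 from -9.20 to -3.27, whereas Hsd3b5 widened from 2.79 to 7.84 and Sult2a1 from -6.33 to -9.88.

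**Figure D4:**
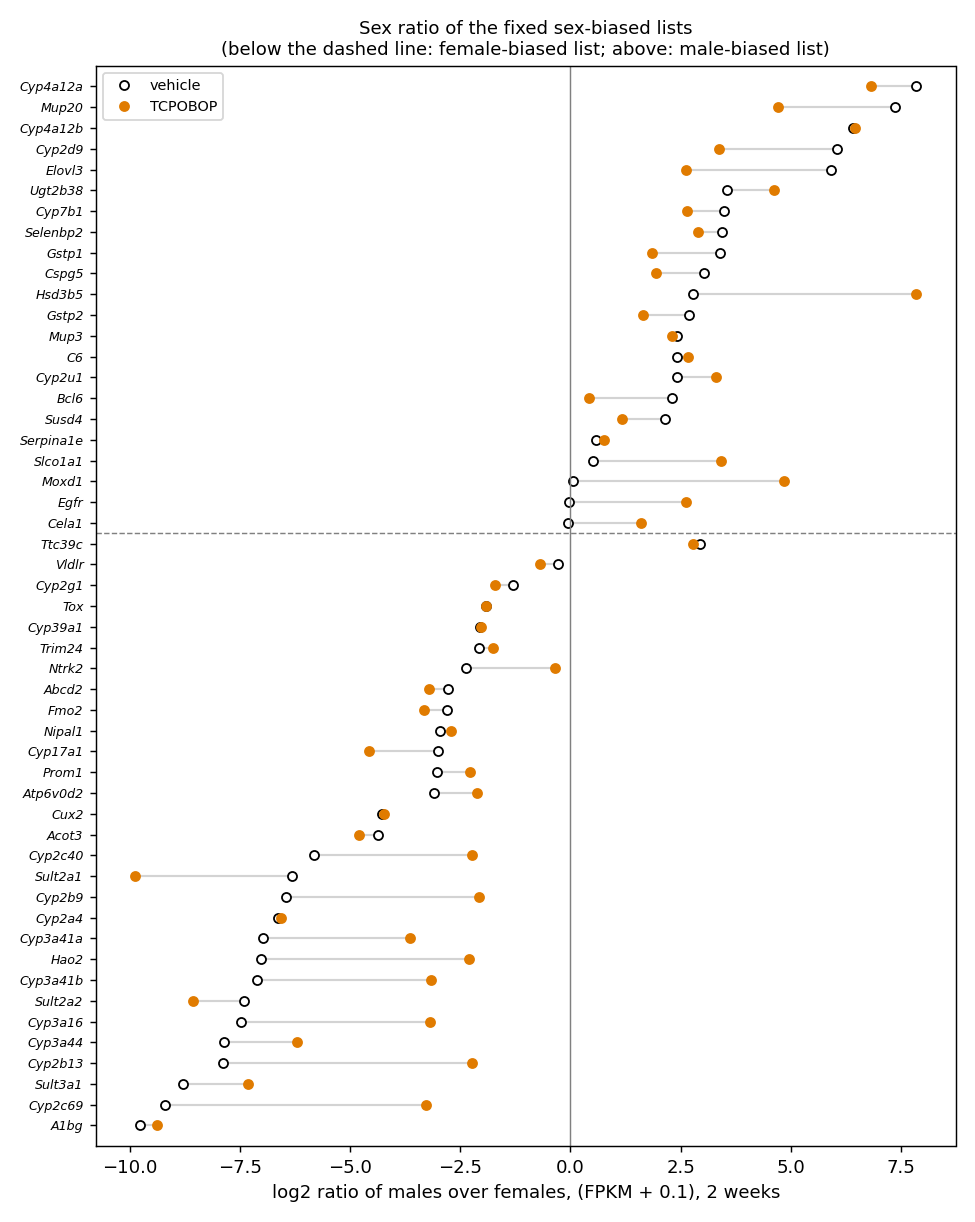
Log2 ratio of males over females of the pooled FPKM values plus 0.1 at 2 weeks for the fixed male-biased (above the dashed line) and female-biased genes, in vehicle (open) and TCPOBOP mice (filled). Mup20 went from 7.37 to 4.71 and Cyp2b13 from -7.88 to -2.25.

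TCPOBOP calls in 8-week males were set against sex bias in 2-week vehicle mice, which share no library. Under high corn oil 26 male-biased genes fell and 18 rose, and 35 female-biased genes rose and 8 fell (two-sided Fisher exact p = 0.000156). Under low corn oil 38 male-biased genes fell and 16 rose, and 38 female-biased genes rose and 8 fell (two-sided Fisher exact p = 1e-07). In 2-week males, whose vehicle libraries also define the bias, 23 male-biased genes fell and 8 rose, and 39 female-biased genes rose and 8 fell. In females, whose vehicle libraries define the bias too, 29 male-biased genes rose and 21 fell, and 28 female-biased genes rose and 36 fell (two-sided Fisher exact p = 0.186). Without the FPKM minimum these were 38 and 28, and 45 and 73 (two-sided Fisher exact p = 0.0135). Chance values of the shared vehicle libraries favour the direction seen in each sex at 2 weeks. The 2-week counts therefore do not tell a response of sex-biased genes from such chance. Over all sex-biased genes, called or not, the medians of male-biased and female-biased genes were 0.03 and -0.09 under high and -0.20 and 0.14 under low corn oil.

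Responses of males and females were then compared gene by gene with the approximate test, which called 112 of 12253 genes, 71 with the larger log2 fold change in males and 41 in females. Cyp2b13, Cyp2b9 and Hao2, female-biased in vehicle mice, had log2 fold changes of 7.50, 4.32 and 6.32 in males and 1.17, -0.08 and 0.52 in females in the authors' deposited table. Hsd3b5 and Cyp2c69 had -0.55 and -1.06 in males and -6.62 and -6.37 in females, and the growth factor receptor gene Egfr 0.42 and -2.21 in the authors' deposited table. In the other direction Sult2a1 had 0.30 in males and 3.74 in females, Elovl3, a fatty acid elongase, -0.81 and 2.67, and Ces2c, a carboxylesterase, 1.72 and 4.62 in the authors' deposited table. Cyclin D1 (Ccnd1) had 1.75 and 0.44, and Cdkn1a 0.86 and -2.26 in the authors' deposited table. By list, 5 of 18 phase I enzymes tested had the higher log2 fold change in females and none in males, and 8 of 28 female-biased genes had the higher log2 fold change in males against 1 in females. No member of the lipid, glucose, zonation or acute phase lists was called, in a test that recovered 10% of simulated log2 differences of 1.

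Between regimens at 8 weeks the approximate test called 18 of 12353 genes, 9 in each direction. Library set, later dose, DMSO share and the age of some vehicle mice differ between the regimens too. These differences can therefore not be ascribed to corn oil volume. Cish had log2 fold changes of -0.38 under high and 3.72 under low corn oil, the interferon-signalling gene Irf9 -1.98 and 1.70, Gadd45g -1.73 and 1.68, and Myc 0.23 and 2.15 in the authors' deposited table. The Gadd45g call was lost with another un-adjustment of the p-values (adjusted p = 0.0572). For Cish the vehicle groups were further apart than the TCPOBOP groups. It stood at 32.3 FPKM under high and 1.07 FPKM under low corn oil in vehicle, against 23.5 and 15.3 FPKM with TCPOBOP. The response of Moxd1, at 5.19 under high corn oil, was larger by 3.79 than under low, and Selenbp2, a male-biased gene, had 0.60 and -1.64 in the authors' deposited table. Duration was examined in males under low corn oil, where 46 of 12305 genes were called between 8 and 2 weeks, 23 in each direction. Vldlr, a lipoprotein receptor, had log2 fold changes of 1.71 at 8 and -0.25 at 2 weeks, Cyp7a1 0.04 and -1.92, Cyp39a1 2.70 and 0.40, Thrsp -0.24 and 2.04 and the imprinted RNA Meg3 -2.67 and 1.21 in the authors' deposited table. Of 8 weeks high against 2 weeks low corn oil, 37 of 12131 genes were called, 18 higher and 19 lower. Apoa4 had 4.86 and 1.44, Vldlr 1.57 and -0.25, Mup20 3.04 and 0.69, and Orm2 1.42 and 3.12 in the authors' deposited table. Duration is confounded with library set in the low corn oil contrast and with oil volume in the other, and age differs in both. Dosing differs in both too, since later doses were given only to the 8-week TCPOBOP mice.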

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

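All tests weighed in this part, and the approximate test of a difference between responses, were chosen after the table and the results they concern were seen. The genes below are among those of the fixed rule and list members that this approximate test called different between 2 groups. All differences are of log2 fold changes computed from the authors' deposited table.

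The response at 2 weeks differed between males and females in 112 genes. The log2 fold change was lower in males than in females, as males minus females, for Prss22 (-7.90), Gm3776 (-4.69), Cyp2c53-ps (-4.68), Mir3968 (-3.61), Elovl3 (-3.48), Sult2a1 (-3.44), Ces2c (-2.90), Mup20 (-2.72), Gsta2 (-2.59) and Bcl6 (-2.01) in values from the authors' deposited table. It was higher in males than in females for Sult1d1 (1.16), Ccnd1 (1.31), Hbb-b1 and Hbb-bs (1.45 each), Cela1 (1.67), Egfr (2.63), Cdkn1a (3.12), Meg3 (3.24), Cyp2c40 (3.50), Cyp2b9 (4.40), Cyp2c69 (5.31), Hao2 (5.80), Hsd3b5 (6.07), Cyp2b13 (6.33), Hbb-b2 and Hbb-bt (6.53 each) and 4930404H11Rik (7.41) in values from the authors' deposited table. The globin genes and the Cyp2c, Cyp2b and Gst paralogs share reads, so their differences are uncertain.

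High minus low corn oil differed in 18 genes at 8 weeks: Gm3219 (-6.82), Clec2h (-4.39), Cish (-4.10), Irf9 (-3.68), Gadd45g (-3.41), Myc (-1.92), Slc13a2 (1.85), Selenbp2 (2.24), Hspb1 (2.62), Moxd1 (3.79) and G530011O06Rik (5.15) were the named ones in values from the authors' deposited table. With another un-adjustment of the p-values 14 of the 18 stayed, and Gadd45g and G530011O06Rik did not (adjusted p = 0.0572 and 0.0601), while Hspb1 was lost among genes of at least 2 FPKM (adjusted p = 0.0541). G530011O06Rik stood at 0.552 FPKM in high and 11.1 FPKM in low corn oil vehicle males, against 0.826 and 0.510 FPKM with TCPOBOP in the authors' deposited table.

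Between 8 and 2 weeks under low corn oil 46 genes differed. Those named were 4930404H11Rik (-7.80), Derl3 (-5.94), Meg3 (-3.88), C730036E19Rik (-3.86), Mir1906-1 (-3.78), S100a8 (-3.68), Thrsp (-2.28), Apoa4 (1.82), Vldlr (1.96), Cyp7a1 (1.96), Cyp39a1 (2.30), Slpi (3.05), Mir7678 (3.14), Cish (3.74), H2-Ea-ps (6.11) and Dmbt1 (9.22) in values from the authors' deposited table. The other un-adjustment kept 29 of the 46, without Mir7678 and Mir1906-1 (adjusted p = 0.0631 and 0.0664). Vehicle groups differed in some of these genes: Dmbt1 stood at 5.97 FPKM in vehicle males at 2 weeks and at 0.0428 FPKM in the low corn oil vehicle males of the 8-week comparison, against 0.156 and 0.699 FPKM with TCPOBOP, and Cish at 8.57 and 1.07 FPKM in vehicle, against 8.90 and 15.3 FPKM with TCPOBOP in the authors' deposited table. Between 8 weeks of high and 2 weeks of low corn oil 37 genes differed. Those named were 4930404H11Rik (-8.23), Camk2b (-6.72), Gm3219 (-6.19), H2-T23 (-5.61), AF357359 (-3.55), Meg3 (-3.33), Orm2 (-1.70), Vldlr (1.82), Mup20 (2.35), Cyp39a1 (2.52), Sult2a1 (3.38), Apoa4 (3.42), Gm3776 (3.61), Cdh9 (5.69) and Dmbt1 (8.55) in values from the authors' deposited table. The same un-adjustment kept 24 of these 37, without Camk2b, Dmbt1 and Sult2a1 (adjusted p = 0.0522, 0.0562 and 0.0745), and Sult2a1 was also lost with no FPKM minimum (adjusted p = 0.0721).

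A first pattern was weighed for 1597 genes called between the TCPOBOP males of both regimens, those of at least 0.5 FPKM in a vehicle male group. Of these, 94.1% went the same way between vehicle males of high and low corn oil (median signed log2 ratio 0.48, bootstrap interval 0.46 to 0.50 over genes, which are not independent). Vehicle males of 1 library set that differ in corn oil, age and treatment length had a median of 0.06 (0.0581), which does not decide on corn oil volume or age without library set, since opposite effects of these would cancel. The library set could be the source, since vehicle males of both sets under low corn oil had a median of 0.42 in the same direction, in 85.3% of genes, but they also differ in age and treatment length, so these cannot be told apart. For the 13 acute phase genes it stays undecided, with a median of 0.67 (0.34 to 0.88) between the sets against 0.81 (0.36 to 2.02) within 1 set, as Saa1 stood at 359 FPKM in vehicle males of high corn oil and at 20.1 and 18.8 FPKM in both low corn oil groups of the authors' deposited table.

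A second pattern was that called genes in TCPOBOP males at 8 weeks were more often lower if male-biased and higher if female-biased, whereas over all sex-biased genes the medians were 0.03 and -0.09 under high corn oil, where neither fixed list passed. Chance values of the vehicle libraries that define the bias were argued against, since the 8-week comparisons share no library with them and the larger of both Fisher p was 0.000156. Drug-metabolism gene families and their shared reads were argued against as the whole cause, since the larger Fisher p without them was 0.00963. Without these families 20 male-biased genes fell and 13 rose and 20 female-biased genes rose and 7 fell under high corn oil, and 27 fell, 13 rose, 25 rose and 8 fell under low. A change of sex-dependent hormone signalling by the treatment stays open and was not tested, as does a difference in age between vehicle and treated mice under low corn oil.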

How the results depend on the processing

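Of these alternatives, the adjusted p of 0.01, the FPKM ratio with a pseudocount of 0.1, all those of the 2-week sex-bias tests, the 4-fold sex ratio, the removal of drug-metabolism families, the settings of the approximate test other than no FPKM minimum, and the narrower random lists were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate.

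At an adjusted p under 0.01 the higher and lower genes numbered 379 and 210 in 2-week males, 550 and 436 in 2-week females, 612 and 210 and 571 and 361 in 8-week males under high and low corn oil, and 452 and 496 between both TCPOBOP groups, fewer by construction. With FPKM ratios and a pseudocount of 1, the genes of at least 2-fold numbered 166 and 58, 257 and 128, 266 and 120, 224 and 112, and 61 and 109 in the same order. The pseudocount makes low genes count for less by construction, and the ratio also drops the authors' scaling between groups. The share of each was not tested. With a pseudocount of 0.1 the lower genes of 2-week males numbered 147 and the higher genes between both TCPOBOP groups 127; the cause was not tested.

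With no FPKM minimum, which adds genes by construction, 285 genes were male-biased and 484 female-biased in vehicle mice, 369 and 421 in TCPOBOP mice, and 357 were higher and 391 lower in vehicle males of high over low corn oil. With a pseudocount of 1, 106 were female-biased in vehicle mice and 90 lower in vehicle males of high over low corn oil. Un-adjusting p-values over genes above 0 FPKM left 13 genes with the higher log2 fold change at 8 rather than 2 weeks under low corn oil and 9 for 8 weeks high against 2 weeks low; the cause was not tested.

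The other 98 recomputed counts and tests of the comparisons kept their size or side, including every overlap test and the sex-bias tests of males. In 2-week females the sex-bias test gained its side with no FPKM minimum, with 39.7% of called sex-biased genes lower if male-biased or higher if female-biased. Chance values of the vehicle libraries shared with the definition favour that side, so no conclusion is drawn from it. Of the genes whose responses differed, 94 to 112 of 112 by sex, 14 to 18 of 18 by regimen, 29 to 46 of 46 by duration under low corn oil and 24 to 37 of 37 across regimens were called under each alternative. Of single-gene differences 151 kept their side and 9 lost it, none reversed. The 1106 recomputed folds of named genes kept their direction, with the deposited p held fixed. Of list tests 321 kept their side, 14 lost it, 9 gained it, and 1 reversed: cholangiocyte markers in 8-week males under low corn oil, with a median of -0.17 among genes of at least 0.5 FPKM. The cause was not tested. With a pseudocount of 1 the gains were lipid uptake (adjusted p = 0.0207) and male-biased genes (0.0326) in 2-week males. In 8-week males growth arrest (0.023) and macrophage lists (0.0468) gained under high, and macrophage (0.0299) and bile acid lists (0.0464) under low corn oil. With 0.1 they were lipid uptake in 2-week males (0.0322) and male-biased genes between both TCPOBOP groups (0.0454). The last was cholangiocyte markers in 2-week females, among genes of at least 0.5 FPKM (0.0216).

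Not run, as they need values per library, were RLE, upper-quartile and DESeq2 scaling or tests, count filters, fits of only the groups compared, the replicate block, leaving out each replicate, age-matched vehicle mice, camera, and sex bias without a fold minimum. What depth limits is unknown, since no library totals are given.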

Other observations

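Some genes not described above were called in several comparisons, all chosen after their values were seen and not tested as groups. In every TCPOBOP comparison, in the order 2-week males, 2-week females, 8-week males under high and under low corn oil, Isg15 rose by 1.75, 1.19, 1.79 and 1.35, Rsad2 by 1.39, 1.51, 2.03 and 1.87 and Usp18 by 2.23, 0.89, 1.88 and 2.00 on the log2 scale in the authors' deposited table. Orm3, an orosomucoid gene, rose from 0.559 to 36.5 FPKM in 2-week males, and by 4.14, 3.14 and 2.96 in the other comparisons of the authors' deposited table. Srxn1, an antioxidant enzyme gene, rose by 1.13, 1.11, 1.92 and 1.36, and the stress gene Trib3 by 1.64, 2.01, 1.34 and 1.09 in the authors' deposited table. The neutrophil granule gene Ngp rose in females and both 8-week comparisons (2.85, 2.78 and 5.77), whereas S100a9, the partner of S100a8, was called in none of the 4 (0.89, 0.71, -0.11 and -0.36 in the authors' deposited table).

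Rian, a long RNA of the same locus as Meg3, rose by 1.76 in 2-week males and had log2 fold changes of -1.66, -1.72 and -1.80 in 2-week females and 8-week males under high and low corn oil in the authors' deposited table. Peg3, expressed from the paternal allele, rose by 1.55, 1.32 and 1.71 in those 3 comparisons and was not called in 2-week males (0.18) in the authors' deposited table. Growth hormone target Socs2 stood at 14.6 FPKM in TCPOBOP males under high and 4.21 FPKM under low corn oil, and Igf1 at 28.9 and 17.1 FPKM in the authors' deposited table. The Y-linked Kdm5d fell in 8-week males under high corn oil, by 1.15, and was lower under high than low corn oil with TCPOBOP, at -1.27 on the log2 scale in the authors' deposited table.

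Both clock tests here, and the clock genes themselves, were chosen after several other gene sets had been looked at and values of these genes had been seen. In TCPOBOP females the clock genes Arntl, Npas2, Clock, Nfil3 and Cry1 had log2 fold changes of -2.53, -2.65, -0.89, -1.46 and -1.19, while Dbp, Ciart, Bhlhe41, Usp2 and Per3 rose by 2.64, 2.24, 1.91, 1.89 and 1.34 and Tef was not called (0.75) in the authors' deposited table. A change that affects all of these transcripts alike, such as RNA yield or scaling, was argued against, since the medians were opposite, at -1.46 for genes that peak with Arntl and 1.90 for those that peak with Dbp. A clock phase that differs between the groups may be the source, from the hour of collection or from the treatment, which stay open because all mice were collected in the same window of the day and no hour per mouse is given. Males at 2 weeks had a median of -0.76 in the first set, with values of -0.92 to 0.20. Their median in the second set was positive, with values of 0.11 to 1.73. The medians of 2-week males were therefore opposite in the same direction as in females, but single genes differed between the sexes. By the approximate test, Arntl differed, at -0.76 in males and -2.53 in females (adjusted p = 0.00296). Npas2 also differed, at 0.20 in males and -2.65 in females (adjusted p = 3.45e-05). The test called no other gene of either set. At 8 weeks both medians were negative, at -0.16 and -0.77 under high and -0.73 and -0.19 under low corn oil. At most 1 gene of each set was called in any comparison of males. Per1, a clock gene in neither set, stood at 2.48 FPKM in vehicle and 1.54 FPKM in TCPOBOP females, lower where the second set was higher.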
